A study of Mus musculus with 77 samples.

How the data were processed

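RNA sequencing libraries of mouse adenocarcinoma cells and colon organoids were taken as the authors deposited them, in 10 tables with 1 line per gene, and 62 of the 63 RNA samples had a column there. Per the labels' protocols, total RNA was extracted 2 h after hormone, libraries were stranded total RNA libraries (TruSeq), and cells and organoids were kept in charcoal-stripped serum before vehicle, aldosterone (10 nM) or corticosterone (100 nM) was added. Per the submitters' processing notes, bcl2fastq 2.20, cutadapt 1.18, Trimmomatic, STAR 2.7.0f, Bowtie2 2.3.4.1, HOMER 4.10.4 and deepTools were used with the mm10 build. Which of these tools belongs to the RNA and which to the chromatin data is not given in the sources used here. Per the file headers, exon reads were counted with HOMER (analyzeRepeats.pl with condensed genes, with the option noadj in 5 tables and raw in 5) and compared with its getDiffExpression.pl. The tables list 24940 or 25124 genes, with 1 exception of 404 genes. The annotation release and the strand setting of the counting are not given in the sources used here, so genes with near-identical copies, such as histone genes, and antisense pairs are uncertain.

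The library columns hold log2 values that the authors made with a variance-stabilizing transformation (vst, named in the header) in the tables of parental MR580C cells and of both organoid lines. In the other 7 tables the deposited values are on a log2 scale that was taken to be the regularized log (rlog), from their values and not from a header. Both transformations pull weakly expressed genes towards a common value, so differences are smaller than deposited fold changes, mostly for low genes, and differ between scales. Each table also gives the authors' deposited log2 fold change, p-value and adjusted p-value of hormone against vehicle, for which the header names no test. The library totals in the column names, per the file headers, ran from 22.68 to 61.12 M reads (mega-reads) with a mean of 39.9 M. Whole reads per gene cannot be recovered from such logs, so no counting interval could be computed, and count models, other scaling factors and another pseudocount were not run. Before the data were examined, a linear unit had been assumed for the tables, with limma on the values as deposited if they turned out to be logs, which is what was done.

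Groups were taken from the labels. In MR580C cells labelled GRKO, aldosterone libraries 2 and 3 were equal within 1e-06 for every gene that varies and were averaged into 1 library. The column names of the GRKO organoids say GRKD, and the label GRKO was used. The tables give no column for 1 corticosterone sample of parental MR cells (replicate 2). The table of corticosterone in MR580C cells labelled GRKO lists 404 genes, nearly all past the threshold, so it was described and not tested, and the contrast between both MR580C lines for corticosterone was not made. The 14 chromatin immunoprecipitation samples were not analysed here. Gene symbols, RefSeq identifiers and coordinates (mm10) are those of the tables. Older symbols were replaced through the alias column of the newer tables for 237 to 240 genes in the tables of MR cells.

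Each hormone comparison was fitted within its own table with limma 3.58.1 in R 4.3.3, with trend, 1 mean per group, no further covariate, 2-sided tests and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Genes that do not vary were left out, and a gene had to reach a linear value of 10 (log2 3.32) in at least as many libraries as the smaller group. The vst tables lie above this value throughout, so there the filter removed nothing. The ± beside a log2 difference is limma's standard error (SE). Differences between responses were limma interactions over both tables, with 1 intercept per line. Where the tables are on different scales (parental MR580C against the other cell lines), the interaction was replaced by a z test on the authors' deposited fold changes and p-values, which takes each p-value to be that of a Wald test (z limited to 37.5). The size of a response was compared with fry (limma) over genes raised or lowered on average across both lines, adjusted over 4 such tests. Overlaps were set beside the number for independent lists and, for shared vehicle libraries, beside 100 simulated draws with genes drawn independently.

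Before the data were examined, 21 gene lists and the rule for named genes were fixed. The lists hold corticosteroid-induced genes, epithelial sodium and potassium transport, circadian clock, immediate-early and AP-1 genes, NF-kB and inflammatory genes, MAPK phosphatases and feedback inhibitors, glucose and lipid metabolism, chaperones, cholesterol synthesis, cell cycle, p53 and growth arrest, extracellular matrix and mesenchymal genes, ribosomal protein genes, replication-dependent histones, and markers of mature colonocytes, goblet cells, colonic stem cells, enteroendocrine and tuft cells, immune cells and mammary epithelium. A list of mitochondrially encoded genes was not analysed here. Lists with at least 5 tested members were tested with camera (limma) with a preset correlation of 0.01 and adjusted over 188 tests. Of these 61 were called, 44 up and 17 down, and 8 held with a correlation estimated per list. Named genes are a panel of 10 (Per1, Sgk1, Fkbp5, Tsc22d3, Zbtb16, Dusp1, Klf9, Scnn1a, Nr3c1 and Nr3c2), the 6 highest and 6 lowest log2 differences among called genes with a mean of at least 50 (log2 5.64) and libraries that do not overlap, up to 4 called members per list, and the 6 most positive and negative differences between responses. The vst tables lie above log2 5.64 throughout, so there the mean of 50 set no limit. Genes at the end of each ranking could be left out. A single gene that this rule selects is not reported here.

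The scripts were tested on simulated data with 200 changed genes, each gene drawn independently as normal noise with the variance that limma had estimated. Deviations that many genes of a library share were not simulated, so false calls in the real data may be more frequent. At log2 changes of 0.25, 0.5 and 1 the fit recovered 67 of 67, 67 of 67 and 66 of 66 genes for aldosterone in MR cells labelled GRKO (13 false calls among 12486 genes) and 66 of 67, 67 of 67 and 66 of 66 in parental MR cells (16 false calls). In WT organoids it recovered 16 of 67, 66 of 67 and 66 of 66 (3 false calls), and in GRKO organoids 46 of 67, 66 of 67 and 66 of 66 (14 false calls), so small changes are often missed in organoids. With no simulated change it called 1, 0, 0 and 2 genes in these comparisons. For the difference between both MR lines it recovered 100 of 100 genes at 0.5 and 100 of 100 at 1 (8 false calls), and for that between the organoid lines 90 of 100 and 100 of 100 (5 false calls). The alternatives tried were other filters on low values, centred library medians, the replicate number as a block, each library left out in turn, the authors' deposited adjusted p-value, the z test in place of the interaction and the reverse, the repeated library counted as 2, and leaving out some libraries or genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.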

Results

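The series asks how mouse cells answer aldosterone, the main mineralocorticoid, and corticosterone, the main glucocorticoid of rodents, when the mineralocorticoid receptor (MR, gene Nr3c2) works with or without the glucocorticoid receptor (GR, gene Nr3c1). Total RNA was sequenced from 63 samples in 18 groups. Adenocarcinoma cells were either parental or labelled GRKO, that is, GR knockout, and carried MR, an MR form that the labels call MR580C, or, in a parental line, no added MR. Colon organoids, cultures of intestinal epithelium grown in a gel, were wild type (WT) or labelled GRKO. Cells and organoids were collected 2 h after vehicle, 10 nM aldosterone or, in cell lines with an added MR, 100 nM corticosterone. Each cell group had 3 samples, except 2 for aldosterone in parental MR cells. Of the 3 corticosterone samples of those cells, replicate 2 had no column in the tables, so 2 were used. WT organoids had 6 samples per group and GRKO organoids 5. Library totals ran from 22.68 to 61.12 M reads (mega-reads) with a mean of 39.9 M. They were lowest in GRKO organoids treated with aldosterone (22.68 to 29.04 M) and highest in cells without MR treated with aldosterone (57.67 to 61.12 M). A further 14 chromatin immunoprecipitation samples were not analysed here. The labels do not say that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Library values are on a compressed log2 scale, so differences understate the change of weakly expressed genes. Where the authors' deposited table is named, its log2 fold change is given without an error.

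Nr3c1 (NM_001361211, chromosome 18, 39410545 to 39489776, mm10 build), the gene targeted in the GRKO samples, stood at 11.24 ± 0.097 (SD, n = 6) in vehicle-treated WT organoids and at 9.12 ± 0.072 (SD, n = 5) in those labelled GRKO. The single libraries lay between 11.15 and 11.42 in the former and between 9.07 and 9.24 in the latter. With aldosterone they lay between 10.5 and 10.85 in WT and between 8.82 and 9.07 in GRKO organoids. In vehicle-treated cells Nr3c1 was 13.00 ± 0.021 (SD, n = 3) in the MR line labelled GRKO and 12.87 ± 0.031 (SD, n = 3) in the parental MR line, so the transcript was not lower in the libraries of this line labelled GRKO. The tables of both MR lines list Nr3c1 as NM_008173 (39410545 to 39487245). It was 11.88 ± 0.032 (SD, n = 3) in MR580C cells labelled GRKO, 13.17 ± 0.04 (SD, n = 3) in parental MR580C cells and 13.52 ± 0.015 (SD, n = 3) in parental cells without MR. Exon reads do not show whether protein is made, and the edit itself is not given in the sources used here, so the cell lines are called "labelled GRKO" and every contrast with the parental lines rests on that label. Nr3c2 (NM_001083906, chromosome 8, 76902330 to 77245012, and 76902508 to 77243639 in the tables of both MR lines) was 4.69 ± 0.0058 (SD, n = 3) in parental cells without MR. It was 10.84 ± 0.031 in parental MR cells, 11.32 ± 0.13 in MR cells labelled GRKO, 11.33 ± 0.015 in parental MR580C cells and 9.70 ± 0.038 in MR580C cells labelled GRKO (SD, n = 3 each). In vehicle organoids it was 11.48 ± 0.12 (SD, n = 6) in WT and 11.74 ± 0.14 (SD, n = 5) in GRKO. These levels come from tables that were normalized separately, so none of the differences between lines was tested. Those of parental MR580C cells and of organoids are on the vst scale, the others on a scale taken to be rlog. Levels on different scales, such as those of both MR580C lines, do not show which line is higher.

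Parental cells without MR served as the background of the aldosterone response. Sgk1, a kinase that promotes epithelial sodium uptake (NM_001161850, chromosome 10, 21993890 to 21999902), differed by 0.02 ± 0.038 (SE) between aldosterone and vehicle (3 libraries against 3), and Tsc22d3, the glucocorticoid-induced leucine zipper GILZ (NM_010286, chromosome X, 140539529 to 140548571), by 0.01 ± 0.024. Per1, a repressor of the circadian clock (NM_011065, chromosome 11, 69098949 to 69109957), differed by 0.09 ± 0.028 with adjusted p = 0.9. Klf10, a transcription factor induced by TGF-beta (NM_013692, chromosome 15, 38294406 to 38300711), fell by 0.31 ± 0.022 (adjusted p = 0.0063), lower in all 3 treated libraries. It was 1 of 13038 genes to pass limma at adjusted p under 0.05, with 597 genes at an unadjusted p under 0.05 and 4 raised and 14 lowered in the authors' deposited table. Without single libraries the count was 0 (each vehicle library or aldosterone 2), 2 (aldosterone 1) or 49 (aldosterone 3, with 12 raised and 37 lowered). Cholesterol synthesis genes were higher as a list, with a positive difference in 20 of 22 and a median of 0.041 (adjusted p = 1.5e-06, and adjusted p = 0.28 with an estimated correlation), although 0 members passed over all genes tested or adjusted over the list alone. The list of p53 and growth arrest genes was lower (median -0.024, adjusted p = 0.00048, and adjusted p = 0.16 with an estimated correlation), with 0 of 17 lowered over all genes tested and 3 adjusted over the list alone.

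In parental MR cells aldosterone raised Tsc22d3 by 1.00 ± 0.024 (SE, 2 libraries against 3, adjusted p = 2.6e-07). The small GTPase gene Arl4d rose by 0.61 ± 0.023, Per1 by 0.57 ± 0.037 and Sgk1 by 0.57 ± 0.035 (adjusted p = 9.5e-05). The authors' deposited table gives 1.89 for Tsc22d3, 2.49 for Per1 and 0.95 for Sgk1. Foxred2, a flavoprotein of the endoplasmic reticulum, rose by 0.56 ± 0.024, and Fkbp5, a co-chaperone of steroid receptors, by 0.26 ± 0.031. The lowered genes included Plk2, a polo-like kinase (-0.33 ± 0.029), Ankrd1, a muscle ankyrin repeat protein (-0.30 ± 0.036), and Ptgs2, the inducible cyclooxygenase (-0.29 ± 0.031). Of 33 corticosteroid-induced genes measured, 15 rose and 0 fell over all genes tested, and 24 rose and 1 fell adjusted over the list alone (median 0.15, adjusted p = 7.5e-40, and adjusted p = 0.041 with an estimated correlation). Of 16 circadian clock genes 4 rose under both adjustments, namely Per1, Bhlhe41, Per2 and Nfil3 (median 0.002, adjusted p = 0.0055, and adjusted p = 0.38 with an estimated correlation). The epithelial transport list was higher (median 0.0029, adjusted p = 0.00087, and adjusted p = 0.23 with an estimated correlation), with 2 of 16 raised over all genes tested and 3 adjusted over the list alone. Ribosomal protein genes were higher as a list (median 0.045, adjusted p = 0.0021, and adjusted p = 0.84 with an estimated correlation) with 0 of 30 passing alone under either adjustment. The NF-kB and inflammatory list was lower by the test (adjusted p = 0.011, and adjusted p = 0.29 with an estimated correlation) and by its median of -0.013, while its mean was 0.019. Of its 18 members 2 rose and 1 fell over all genes tested, and 2 rose and 4 fell adjusted over the list alone. Among them Nfkbia, which encodes an inhibitor of NF-kB, rose by 0.21 ± 0.023. In all, 78 genes rose and 9 fell of 12479 tested, against 108 and 19 in the authors' deposited table. The count fell from 87 to 37 without vehicle 1, 48 without vehicle 2, 43 without aldosterone 1 and 46 without aldosterone 3. Deviations from the group mean correlated over genes, which are not independent, at 0.75 between vehicle 3 and aldosterone 3 and at 0.70 between vehicle 1 and aldosterone 1, the only other aldosterone library. Without both libraries numbered 3, where the lone aldosterone library is assumed to vary like the vehicles, 156 genes rose and 51 fell.

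In MR cells labelled GRKO aldosterone raised Sgk1 by 0.59 ± 0.027 (SE, 3 libraries against 3, adjusted p = 1.6e-09). Per1 rose by 0.30 ± 0.019, Resf1, a factor of retroelement silencing, by 0.28 ± 0.023 and Tsc22d3 by 0.25 ± 0.025 (adjusted p = 2.2e-05). The authors' deposited table gives 0.89 for Sgk1, 1.54 for Per1 and 0.55 for Tsc22d3. Fkbp5 differed by 0.07 ± 0.022 (adjusted p = 0.2) and Klf9, a Krüppel-like factor, by 0.07 ± 0.018 (adjusted p = 0.13). Sphk1, a sphingosine kinase, rose by 0.24 ± 0.026, and Ccn2, a matricellular growth factor, by 0.20 ± 0.019. Of 32 corticosteroid-induced genes 6 rose and 0 fell over all genes tested, and 14 rose and 2 fell adjusted over the list alone (median 0.034, adjusted p = 5.4e-10, and adjusted p = 0.14 with an estimated correlation). The transport list was higher (median 0.0052, adjusted p = 0.017, and adjusted p = 0.31 with an estimated correlation), with 2 of 16 raised over all genes tested, and 2 raised and 1 lowered adjusted over the list alone. Of 22 cholesterol synthesis genes 1 rose over all genes tested, Hmgcs1 (0.14 ± 0.03), and 11 adjusted over the list alone (median 0.059, adjusted p = 3.1e-07, and adjusted p = 0.44 with an estimated correlation). Replication-dependent histone genes, whose transcripts lack a poly(A) tail, fell in 14 of 22 cases over all genes tested and in 20 adjusted over the list alone (median -0.16, adjusted p = 3.6e-30, and adjusted p = 0.25 with an estimated correlation). They were led by Hist4h4 at -0.35 ± 0.047 and Hist1h4j at -0.32 ± 0.051. Beside them Rmrp, the RNA of RNase MRP, fell by 0.47 ± 0.091 and Rn45s, the ribosomal RNA precursor, by 0.41 ± 0.084. In the authors' deposited table Rmrp (adjusted p = 0.25), Rn45s (adjusted p = 0.19) and Hist1h4j (adjusted p = 0.078) did not pass, whereas Hist4h4 did (adjusted p = 0.0068). Ribosomal protein genes were lower as a list (median -0.025, adjusted p = 0.00011, and adjusted p = 0.55 with an estimated correlation). Of 30 such genes 1 was lowered over all genes tested and 3 adjusted over the list alone. In all, 54 genes rose and 70 fell of 12486 tested, against 65 and 77 in the authors' deposited table, and 81 remained with histone genes, Rn45s and Rmrp left out (54 raised, 27 lowered). The count of 124 was 70 without vehicle 1, 436 without vehicle 2, 68 without vehicle 3 and 63 without aldosterone 1. Another split of these libraries, vehicle 1 and 3 with aldosterone 3 against the others, called 173 genes. The count alone therefore does not show an effect of aldosterone.

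**Figure D1:**
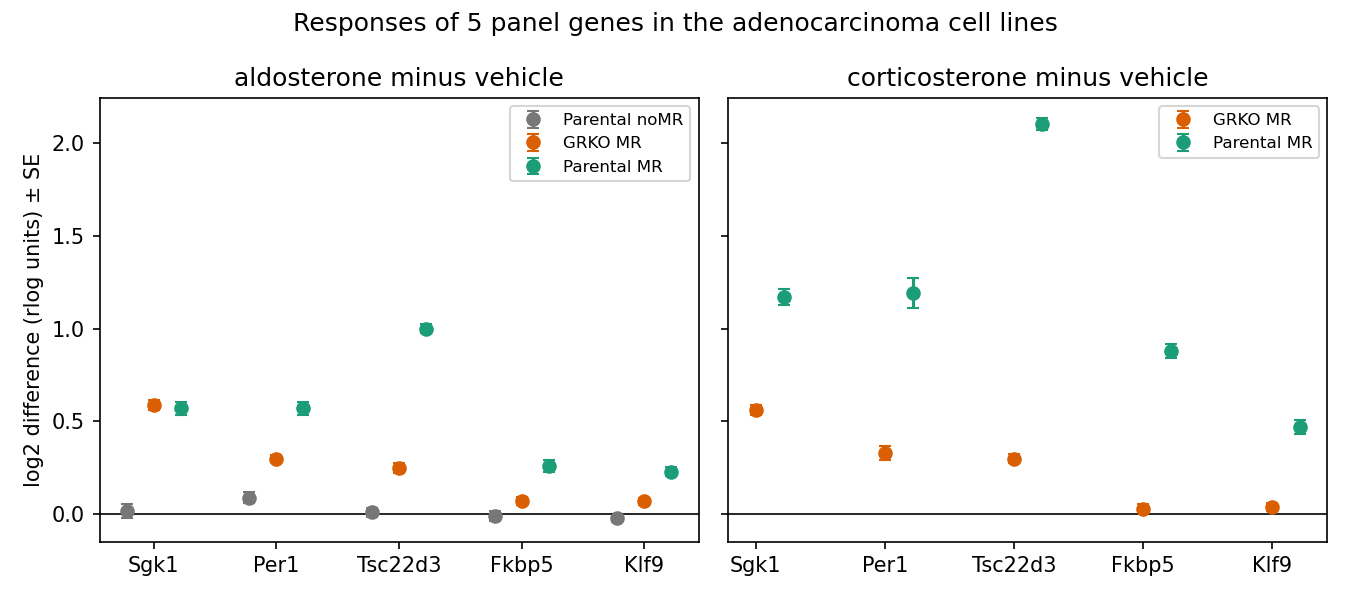
Log2 difference between hormone and vehicle (y axis, rlog units, ± SE from limma) for Sgk1, Per1, Tsc22d3, Fkbp5 and Klf9 (x axis) in parental cells without MR, MR cells labelled GRKO and parental MR cells, with aldosterone at left and corticosterone at right (no corticosterone samples without MR). With aldosterone Sgk1 lies at 0.59 and 0.57 in the 2 MR lines, whereas Tsc22d3 lies at 0.25 and 1.00.

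The contrast between both MR lines addresses whether GR changes the aldosterone response. Tsc22d3 rose by 0.74 ± 0.037 more in parental MR cells than in those labelled GRKO (1.00 against 0.25, adjusted p = 1.8e-07), Arl4d by 0.45 ± 0.027 more and Foxred2 by 0.41 ± 0.027 more. Plin4, a lipid droplet protein, rose by 0.41 ± 0.051 more, the chromatin factor Jade2 by 0.39 ± 0.032 more, and the GTPase Hras by 0.38 ± 0.047 more. Plin4 and Hras moved by -0.04 and 0.00 in the cells labelled GRKO. Per1 (0.27 ± 0.044), Fkbp5 (0.19 ± 0.037) and Klf9 (0.17 ± 0.027) also responded more strongly in parental MR cells, whereas Sgk1 differed by -0.02 ± 0.047 (adjusted p = 0.88). Lgr4, a receptor for R-spondins, was 1 of the 2 genes with a more negative response in parental MR cells (-0.17 ± 0.032). Of 12752 genes tested, 33 differed, 31 with a higher and 2 with a lower response in parental MR cells. Over 124 genes raised on average across the lines the median response was 0.155 in parental MR cells and 0.066 in those labelled GRKO, larger in the former for 111 genes (adjusted p = 2e-06 by limma's fry, over 4 such tests). Of 33 corticosteroid-induced genes 10 were among the genes that differed. Over 29 genes lowered on average the medians were -0.113 and -0.072 (adjusted p = 0.00044 by fry, no longer called with the replicate number as a block). This call was lost without both libraries numbered 3 (median difference -0.011) or without parental MR aldosterone 3 (-0.0345), and the difference turned to 0.0139 without vehicle 2 of the line labelled GRKO. Both lines shared 32 raised genes, of 54 and 76 called among the 12188 genes tested in both (0.34 for independent lists), and 4 lowered genes (0.052 for independent lists). Without both libraries numbered 3 the number of genes that differed was 53.

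Against parental cells without MR, the aldosterone response of parental MR cells was higher for Tsc22d3 by 0.99 ± 0.032, Arl4d by 0.61 ± 0.031 and Foxred2 by 0.58 ± 0.03. It was also higher for Sgk1 by 0.55 ± 0.056 and Bcl2l1, an inhibitor of apoptosis, by 0.51 ± 0.033. It was lower for Smad9, a mediator of BMP signals (-0.30 ± 0.056), Ptgs2 (-0.28 ± 0.049) and Plk2 (-0.27 ± 0.04). Of 33 corticosteroid-induced genes 14 had a higher response, with medians of 0.145 with MR and 0 without. In all, 59 genes were higher and 11 lower of 13162 tested. The count of 70 dropped to 45 without parental MR vehicle 1, 46 without its vehicle 3, 42 without its aldosterone 1, and 43 without its aldosterone 3. It was 42 without vehicle 1 and 45 without vehicle 3 of the cells without MR, and 41 without both parental MR libraries numbered 3.

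Corticosterone, which binds both receptors, raised Tsc22d3 in parental MR cells by 2.10 ± 0.032 (SE, 2 libraries against 3, adjusted p = 3.7e-09) and Arl4d by 1.57 ± 0.034. Spsb1, an adaptor of a ubiquitin ligase, rose by 1.48 ± 0.041, Per1 by 1.19 ± 0.082, Sgk1 by 1.17 ± 0.041 and Fkbp5 by 0.88 ± 0.038. Thbs1, the matricellular protein thrombospondin, fell by 0.69 ± 0.043, Ankrd1 by 0.69 ± 0.043, and Dusp4, a MAP kinase phosphatase, by 0.56 ± 0.032. Of 35 corticosteroid-induced genes 27 rose and 1 fell over all genes tested, and 28 rose and 2 fell adjusted over the list alone (median 0.47, adjusted p = 3.4e-54, and adjusted p = 0.071 with an estimated correlation). The transport list was higher (3 of 16 raised, 4 adjusted over the list alone, adjusted p = 0.003, and adjusted p = 0.27 with an estimated correlation). So was the clock list (4 of 16 raised under both adjustments, adjusted p = 0.017, and adjusted p = 0.38 with an estimated correlation). Chaperones were higher (1 of 20 raised under both adjustments, adjusted p = 0.0084, and adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes were higher too (0 of 30 under both adjustments, adjusted p = 0.017, and adjusted p = 0.84 with an estimated correlation). Cholesterol synthesis genes were lower (1 of 22 lowered, 3 adjusted over the list alone, adjusted p = 0.00039, and adjusted p = 0.38 with an estimated correlation). Extracellular matrix genes were lower as well (2 of 17 lowered, and 1 raised and 3 lowered adjusted over the list alone, adjusted p = 0.018, and adjusted p = 0.52 with an estimated correlation). The NF-kB list was lower by its test (adjusted p = 0.0074, and adjusted p = 0.38 with an estimated correlation) and its median of -0.045 but had a mean of 0.049. Here Nfkbia rose by 0.59 ± 0.033 while Csf1, a macrophage growth factor, fell by 0.40 ± 0.036, with 2 of 18 raised and 4 lowered over all genes tested, and 2 raised and 8 lowered adjusted over the list alone. In all, 259 genes rose and 129 fell of 12460 tested, against 300 and 164 in the authors' deposited table. The total of 388 was 241 without vehicle 1 and 840 without both libraries numbered 3 (410 raised, 430 lowered).

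In MR cells labelled GRKO corticosterone raised Sgk1 by 0.56 ± 0.026 (SE, 3 libraries against 3, adjusted p = 8.8e-07), Per1 by 0.33 ± 0.04 and Tsc22d3 by 0.30 ± 0.024, and Fkbp5 differed by 0.03 ± 0.024. The lowered genes were Epha2, an ephrin receptor (-0.21 ± 0.035), and Fhdc1, a formin (-0.15 ± 0.026). Of 32 corticosteroid-induced genes 4 rose over all genes tested, and 9 rose and 1 fell adjusted over the list alone (median 0.03, adjusted p = 3.1e-06, and adjusted p = 0.15 with an estimated correlation). Cholesterol synthesis genes were higher as a list (median 0.064, 0 of 22 over all genes tested, 11 adjusted over the list alone, adjusted p = 1.7e-07, and adjusted p = 0.28 with an estimated correlation). Aldosterone was set against the same vehicle libraries, so lists that moved alike with both hormones are no independent repeat. Histone genes were lower as a list (median -0.064, adjusted p = 0.00039, and adjusted p = 0.71 with an estimated correlation). Chaperones were also lower (median -0.023, adjusted p = 0.026, and adjusted p = 0.31 with an estimated correlation), like cell cycle genes (median -0.014, adjusted p = 0.026, and adjusted p = 0.66 with an estimated correlation). In these 3 lists 0 members were called over all genes tested or adjusted over the list alone. In all, 29 genes rose and 2 fell of 12517 tested, against 54 and 24 in the authors' deposited table. The 31 calls were 14 without vehicle 1, 17 without vehicle 3, 177 without corticosterone 1 (132 of them lowered), 20 without corticosterone 2 and 18 without corticosterone 3. Another split of these libraries, vehicle 1 and 3 with corticosterone 1 against the others, called 321 genes.

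The corticosterone response was stronger in parental MR cells for Tsc22d3 by 1.80 ± 0.036, Arl4d by 1.38 ± 0.043, Spsb1 by 1.32 ± 0.048, and Tsku, a secreted leucine-rich protein, by 1.05 ± 0.039. Per1 (0.86 ± 0.11), Fkbp5 (0.85 ± 0.043), Sgk1 (0.61 ± 0.047), Dusp1, a MAP kinase phosphatase (0.51 ± 0.053), and Klf9 (0.42 ± 0.037) followed, and 27 of 35 corticosteroid-induced genes had a higher and 1 a lower response. Responses were more negative in parental MR cells for Thbs1 (-0.76 ± 0.046), Ankrd1 (-0.53 ± 0.057), Insig1, a regulator of sterol synthesis (-0.49 ± 0.049), and Nr3c1 itself (-0.19 ± 0.041). In all, 252 genes were higher and 107 lower of 12770 tested. Aldosterone and corticosterone raised 28 genes in common in MR cells labelled GRKO, of 54 and 29 calls, and 76 in parental MR cells, of 78 and 250 calls, against 0.13 and 1.6 for independent lists. They lowered 2 and 8 in common, against 0.011 and 0.094. Both hormones were set against the same vehicle libraries. In 100 simulated draws with no effect, top lists of the same lengths shared a mean of 4.92 raised genes (highest 11) in the former line and 18.5 (highest 26) in the latter. For lowered genes they shared 0.76 (highest 2) and 3 (highest 6), so the 2 shared in the former line did not exceed the highest draw. The draws took genes as independent and leave out deviations that many genes of a vehicle library share. Part of either overlap may come from the shared vehicles, which are too few to split.

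In parental MR580C cells aldosterone raised Per1 by 1.75 ± 0.036 (SE, 3 libraries against 3, adjusted p = 1.3e-17), Tsc22d3 by 1.29 ± 0.046, Foxred2 by 1.06 ± 0.037 and Jade2 by 0.84 ± 0.037. The copper protein ceruloplasmin (Cp) rose by 0.66 ± 0.081, Sgk1 by 0.56 ± 0.038 and the receptor transcript Nr3c2 by 0.29 ± 0.031. The values do not tell the added MR from the cells' own Nr3c2, so induction of that gene is not shown. Ptgs2 fell by 0.51 ± 0.043 and Csf1 by 0.39 ± 0.044. Of 40 corticosteroid-induced genes 15 rose over all genes tested and 23 adjusted over the list alone (median 0.09, adjusted p = 2.9e-29, and adjusted p = 0.006 with an estimated correlation). Of 19 clock genes 5 rose, and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.00027, and adjusted p = 0.21 with an estimated correlation). Transport genes were higher as a list (3 of 30 raised, and 4 raised and 2 lowered adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.16 with an estimated correlation). Glucose and lipid metabolism was higher (3 of 24 raised, and 4 raised and 1 lowered adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.44 with an estimated correlation), and so was cholesterol synthesis (1 of 22 raised, and 7 raised and 1 lowered adjusted over the list alone, adjusted p = 1.4e-07, and adjusted p = 0.16 with an estimated correlation). The p53 list was higher too (2 of 18 raised, and 7 raised and 1 lowered adjusted over the list alone, adjusted p = 0.0056, and adjusted p = 0.15 with an estimated correlation). Cell cycle genes were lower (1 of 28 lowered under both adjustments, adjusted p = 9.3e-05, and adjusted p = 0.38 with an estimated correlation). Histone genes were lower as well (0 of 22 under both adjustments, adjusted p = 0.028, and adjusted p = 0.75 with an estimated correlation). In all, 135 genes rose and 81 fell of 18787 tested, against 133 and 89 in the authors' deposited table, with 80 calls without vehicle 3 and 119 without aldosterone 2.

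Corticosterone in the same cells raised Per1 by 2.74 ± 0.036 (SE, 3 libraries against 3, adjusted p = 2e-21), Tsc22d3 by 2.50 ± 0.046, Hras by 1.84 ± 0.037, Spsb1 by 1.82 ± 0.036 and Sgk1 by 1.70 ± 0.038. Ptgs2 fell by 0.93 ± 0.043, Phlda1, a pleckstrin homology domain protein, by 0.88 ± 0.041 and Thbs1 by 0.82 ± 0.067. Of 40 corticosteroid-induced genes 28 rose and 1 fell over all genes tested, and 29 rose and 1 fell adjusted over the list alone (median 0.58, adjusted p = 1e-62, and adjusted p = 0.00094 with an estimated correlation). Immediate-early and AP-1 genes were lower as a list (median -0.056, adjusted p = 0.046, and adjusted p = 0.58 with an estimated correlation), with 4 of 27 raised and 8 lowered over all genes tested, and 4 raised and 10 lowered adjusted over the list alone. Among them Zfp36, which destabilizes cytokine mRNA, rose by 1.18 ± 0.037 and Fosl2, an AP-1 subunit, fell by 0.75 ± 0.038. The p53 list was higher (7 of 18 raised and 2 lowered, 8 and 2 adjusted over the list alone, adjusted p = 0.0012, and adjusted p = 0.12 with an estimated correlation). Transport genes were higher (6 of 30 raised and 1 lowered, 7 and 2 adjusted over the list alone, adjusted p = 0.0096, and adjusted p = 0.15 with an estimated correlation), as were clock genes (5 of 19 raised and 1 lowered, 5 and 4 adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.38 with an estimated correlation). Chaperones were higher (1 of 20 raised, 2 adjusted over the list alone, adjusted p = 0.046, and adjusted p = 0.44 with an estimated correlation). Cell cycle genes were lower (1 of 28 raised and 1 lowered under both adjustments, adjusted p = 0.028, and adjusted p = 0.63 with an estimated correlation). In all, 649 genes rose and 651 fell, against 775 and 836 in the authors' deposited table, and the 1300 calls were 805 without vehicle 3, 761 without corticosterone 2 and 849 without corticosterone 3. Set directly against aldosterone, corticosterone gave higher values of Hras by 1.39 (95% confidence interval 1.31 to 1.46), Spsb1 by 1.35 (1.27 to 1.42), Tsc22d3 by 1.21 (1.11 to 1.31) and Sgk1 by 1.13 (1.05 to 1.21). Values were lower for Thbs1 (-0.85, interval -0.99 to -0.71) and Phlda1 (-0.69, interval -0.77 to -0.60). Both hormones are closely related steroids, but the dose was 10 nM for aldosterone and 100 nM for corticosterone, so the comparison is not at matched dose. It gave 372 genes higher and 258 lower with corticosterone, 630 in all and 380 without corticosterone 2. Scnn1a, a subunit of the epithelial sodium channel, differed by 0.03 (interval -0.04 to 0.10) between both hormones, but at 9.34 and 9.31 it lay near the lowest value of the table (9.16), where differences are compressed, so this does not show equal responses.

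In MR580C cells labelled GRKO, aldosterone replicates 2 and 3 held the same value for 17639 of 17639 genes that vary (largest difference 1e-13), which is less than sampling noise, and were counted as 1 sample. Aldosterone raised Per1 by 0.86 ± 0.036 (SE, 2 libraries against 3, adjusted p = 2.8e-06), Foxred2 by 0.48 ± 0.033, Tsc22d3 by 0.43 ± 0.032, Ier2 by 0.40 ± 0.039 and Sgk1 by 0.36 ± 0.033. The lowered genes included Fosl2 (-0.24 ± 0.032), the small GTPase gene Rhob (-0.24 ± 0.031) and Trib3, a stress-induced pseudokinase (-0.23 ± 0.034). Of 32 corticosteroid-induced genes 4 rose and 1 fell over all genes tested, and 9 rose and 1 fell adjusted over the list alone (adjusted p = 7.7e-08, and adjusted p = 0.21 with an estimated correlation). Cholesterol synthesis genes were higher as a list (0 of 22 over all genes tested, 5 raised and 1 lowered adjusted over the list alone, adjusted p = 0.045, and adjusted p = 0.51 with an estimated correlation). In all, 27 genes rose and 10 fell of 12418 tested, whereas the authors' deposited table, whose columns hold the repeated library as 2, calls 324 and 229, and 683 genes were called here when it was counted as 2. The 37 calls were 6, 5 and 13 without vehicle 1, 2 and 3, 2377 without aldosterone 1 and 525 without aldosterone 2, so this count has little weight. For corticosterone the table of this line lists 404 genes, with a highest adjusted p of 0.0504, so it was not tested here. Of these, 402 have an adjusted p under 0.05 in the authors' deposited table, with 176 raised and 226 lowered. The authors' deposited table gives 1.70 for Per1, 1.02 for Tsc22d3, 0.30 for Klf9 and 0.26 for Sgk1.

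A last set of contrasts put the receptor forms and lines side by side. Between MR580C lines, on the fold changes of the authors' deposited table, the aldosterone response was higher in parental cells for Tsc22d3 (difference 1.27, adjusted p = 2.1e-21) and Per1 (1.03, adjusted p = 1.7e-14). It was lower for Ier2 (-0.94) and Ccn1, a matricellular protein (-0.66), while Sgk1 differed by 0.09 (adjusted p = 0.85). A z test on those fold changes called 50 genes higher and 77 lower in parental cells. The deposited p-values counted the repeated library as 2, so this test is too lenient, and limma across both scales called 27. The median difference over 201 genes raised on average was -0.043 in the authors' deposited table and 0.112 by limma across both scales, so no direction is given. In lines labelled GRKO, the response of Sgk1 was 0.23 ± 0.045 higher with MR than with MR580C (adjusted p = 0.029) and the difference of Ier2, an immediate-early gene, was -0.46 ± 0.045 (-0.06 against 0.40, adjusted p = 0.00029). The difference of Per1 was -0.55 ± 0.041 on the rlog scale, but the authors' deposited table differs by only -0.26 (z test adjusted p = 0.5). Here 32 genes were higher and 44 lower by limma. That total of 76 ranged from 24 to 1751 without single libraries. It was 26, 49 and 34 without MR vehicle 1, 2 and 3, and 27, 24 and 40 without MR aldosterone 1, 2 and 3. It was 48 and 229 without MR580C vehicle 1 and 3, and 1751 and 390 without MR580C aldosterone 1 and 2. Between both parental lines the z test on the authors' deposited table gave a higher response with MR for Arl4d (1.06, adjusted p = 2e-08) and a lower one for Txnip, an inhibitor of thioredoxin (-0.76, adjusted p = 0.011). Sgk1 (0.29, adjusted p = 0.14), Tsc22d3 (-0.32, adjusted p = 0.71) and Per1 (-0.34, adjusted p = 1) did not pass. It called 19 genes higher and 8 lower. Limma across both scales called 7, with Arl4d (0.39) still called, Txnip (-0.32) no longer called and Per1 passing.

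**Figure D2:**
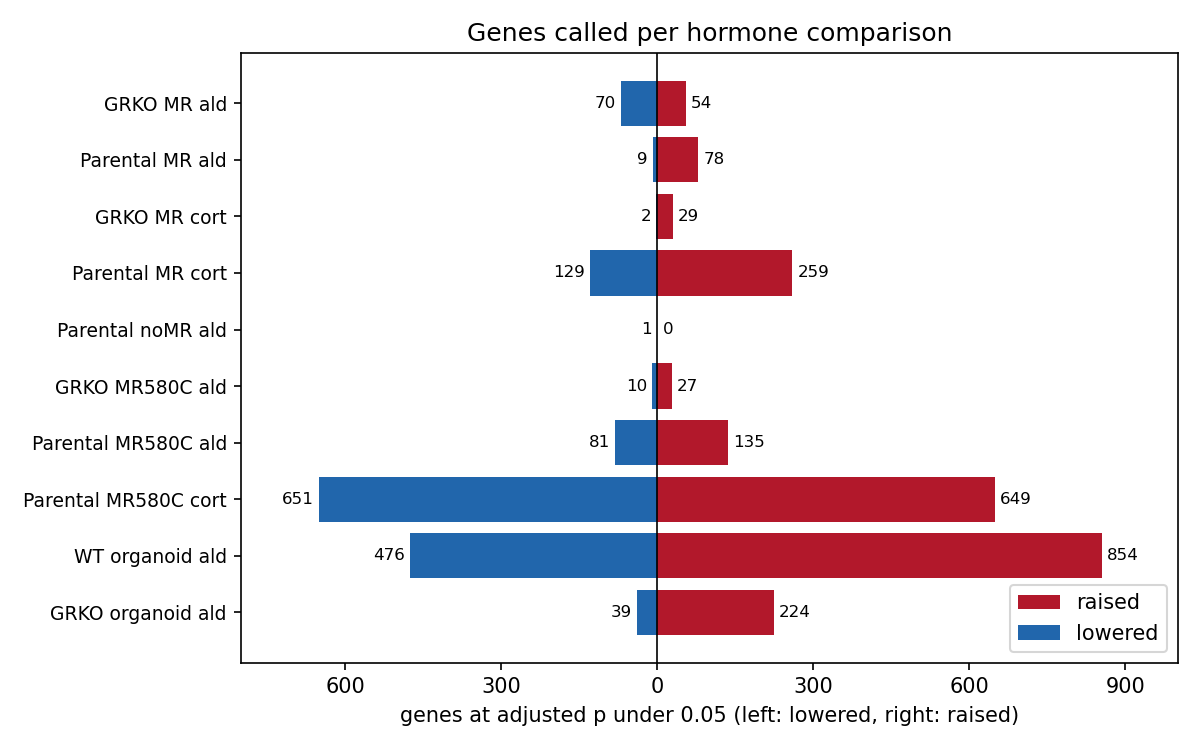
Number of genes at adjusted p under 0.05 by limma in each hormone comparison (x axis, raised to the right and lowered to the left, zero in the middle), 1 bar pair per line and hormone. WT organoids have 854 raised and 476 lowered genes and GRKO organoids 224 and 39, while parental cells without MR have 0 and 1. The numbers of libraries and the scale of the values differ between comparisons.

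In WT colon organoids aldosterone raised Sgk1 (NM_011361, chromosome 10, 21994666 to 21999902) by 5.68 ± 0.076 (SE, 6 libraries against 6, adjusted p = 5.8e-19), from 8.81 ± 0.18 to 14.48 ± 0.11 (SD, n = 6). Angptl4, an inhibitor of lipoprotein lipase (NM_020581, chromosome 17, 33774900 to 33781575), rose by 3.59 ± 0.075. Scnn1g, the gamma subunit of the epithelial sodium channel (NM_011326, chromosome 7, 121734479 to 121768482), rose by 3.24 ± 0.11. Depp1, an autophagy regulator, rose by 3.08 ± 0.11, Ly6m by 3.02 ± 0.12, the transcription factor Zbtb16 by 2.86 ± 0.1, Fkbp5 by 2.72 ± 0.058, the sodium-hydrogen exchanger Slc9a3 by 2.28 ± 0.071, Per1 by 2.13 ± 0.069 and Tsc22d3 by 2.09 ± 0.07. In the authors' deposited table Scnn1g stands at 6.47 and Zbtb16 at 6.44. Cdkn2b, a cell cycle inhibitor, fell by 1.16 ± 0.078, the endothelial lipase gene Lipg by 1.03 ± 0.066, Irf1, an interferon regulatory factor, by 0.87 ± 0.068 and Nr3c1 by 0.53 ± 0.064. Scnn1a, the alpha subunit of the channel, differed by 0.00 ± 0.075. Of 41 corticosteroid-induced genes 31 rose over all genes tested and 35 adjusted over the list alone (median 0.73, adjusted p = 3.1e-60, and adjusted p = 0.00038 with an estimated correlation). Of 35 transport genes 13 rose over all genes tested, and 17 rose and 2 fell adjusted over the list alone (median 0.16, adjusted p = 5.4e-15, and adjusted p = 0.016 with an estimated correlation). Of 26 metabolism genes 12 rose and 2 fell, and 13 rose and 3 fell adjusted over the list alone, with Txnip at 1.01 ± 0.07 and Ppargc1a, a coactivator of mitochondrial genes, at 0.86 ± 0.067 (adjusted p = 5.5e-09, and adjusted p = 0.039 with an estimated correlation). In all, 854 genes rose and 476 fell of 20196 tested, against 1015 and 630 in the authors' deposited table.

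Other lists moved in WT organoids as well. Of 30 immediate-early genes 11 rose and 2 fell, and 12 rose and 3 fell adjusted over the list alone, with Arc at 1.93 ± 0.1 and Klf4 at -0.72 ± 0.08 (adjusted p = 7.2e-05, and adjusted p = 0.39 with an estimated correlation). Of 19 p53 and growth arrest genes 8 rose and 1 fell, and 8 rose and 3 fell adjusted over the list alone, led by Pmaip1, which promotes apoptosis (1.58 ± 0.077), and Sesn1, a stress sensor (1.47 ± 0.078), with adjusted p = 3.2e-07 and adjusted p = 0.15 with an estimated correlation. Clock genes were higher as a list (5 of 19 raised and 2 lowered, 6 and 3 adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.52 with an estimated correlation), among them Cry2 and Nfil3 at 1.20 each. Extracellular matrix genes were higher (3 of 20 raised under both adjustments, adjusted p = 0.0084, and adjusted p = 0.44 with an estimated correlation). Goblet cell markers were higher (1 of 16 raised under both adjustments, adjusted p = 0.017, and adjusted p = 0.28 with an estimated correlation), the raised member being Best2 (1.17 ± 0.11). Cell cycle genes were lower (median -0.10, adjusted p = 0.00039, and adjusted p = 0.54 with an estimated correlation), with 1 of 28 raised and 2 lowered, and 1 raised and 4 lowered adjusted over the list alone. The raised member was Rrm2, a subunit of ribonucleotide reductase (0.79 ± 0.065). Lists that did not pass were NF-kB genes (adjusted p = 0.72), MAPK phosphatases and feedback inhibitors (0.68), chaperones (0.85), cholesterol synthesis (0.59), ribosomal protein genes (0.39) and histones (0.95). Chaperones had a median of -0.059 and a mean of 0.095, cholesterol synthesis genes a median of 0.0028 and a mean of -0.029, and stem cell markers a median of -0.027 and a mean of 0.025. The markers of mature colonocytes (0.11), colonic stem cells (0.89), enteroendocrine and tuft cells (0.72), immune cells (0.71) and mammary epithelium (0.38) did not pass either.

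In organoids labelled GRKO aldosterone raised Sgk1 by 4.05 ± 0.07 (SE, 5 libraries against 5, adjusted p = 5.2e-15), from 9.15 ± 0.056 to 13.20 ± 0.18 (SD, n = 5). Scnn1g rose by 2.47 ± 0.09, Slc9a3 by 1.95 ± 0.081, Fkbp5 by 1.92 ± 0.047, Zbtb16 by 1.60 ± 0.082, Fam43a by 1.51 ± 0.077, Per1 by 1.37 ± 0.069, Tsc22d3 by 1.20 ± 0.064 and Angptl4 by 0.86 ± 0.051. Lipg fell by 0.38 ± 0.059 and Irf1 by 0.35 ± 0.055, whereas Nr3c1 differed by -0.20 ± 0.056 (adjusted p = 0.13). Of 40 corticosteroid-induced genes 14 rose and 1 fell over all genes tested, and 21 rose and 2 fell adjusted over the list alone (median 0.18, adjusted p = 6.6e-27, and adjusted p = 0.083 with an estimated correlation). Of 35 transport genes 10 rose over all genes tested and 15 adjusted over the list alone (median 0.15, adjusted p = 1.6e-22, and adjusted p = 0.041 with an estimated correlation). The p53 list was higher, with 3 of 19 raised, and 7 raised and 1 lowered adjusted over the list alone, led by Trp53inp1 at 0.95 ± 0.058 (adjusted p = 7.8e-09, and adjusted p = 0.039 with an estimated correlation). Immediate-early genes were higher (7 of 30 raised, and 11 raised and 1 lowered adjusted over the list alone, adjusted p = 6e-07, and adjusted p = 0.28 with an estimated correlation). Metabolism genes were higher (4 of 26 raised and 1 lowered, 6 and 1 adjusted over the list alone, adjusted p = 0.00011, and adjusted p = 0.4 with an estimated correlation). Markers of mature colonocytes were higher (2 of 20 raised, 4 adjusted over the list alone, adjusted p = 7e-07, and adjusted p = 0.28 with an estimated correlation). Goblet cell markers were higher (2 of 16 raised under both adjustments, adjusted p = 0.00019, and adjusted p = 0.39 with an estimated correlation). So were those of mammary epithelium (0 of 20 under both adjustments, adjusted p = 0.028, and adjusted p = 0.34 with an estimated correlation). Cell cycle genes were lower (0 of 28 under both adjustments, adjusted p = 0.0033, and adjusted p = 0.75 with an estimated correlation). Histone genes were lower (0 of 22, 2 lowered adjusted over the list alone, adjusted p = 0.00034, and adjusted p = 0.52 with an estimated correlation). In all, 224 genes rose and 39 fell of 20050 tested, against 364 and 104 in the authors' deposited table. The 263 calls were 970 without vehicle 1 (642 raised, 328 lowered), 174 without vehicle 2 and 171 without aldosterone 3, and 1025 without vehicle 1 and 2, the libraries highest in Paneth cell genes. Of these genes Lyz1, a lysozyme, stood 4.78 ± 0.92 (SD, n = 5) above the lowest table value in vehicle GRKO organoids and 3.31 ± 0.29 (SD, n = 6) in WT.

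**Figure D3:**
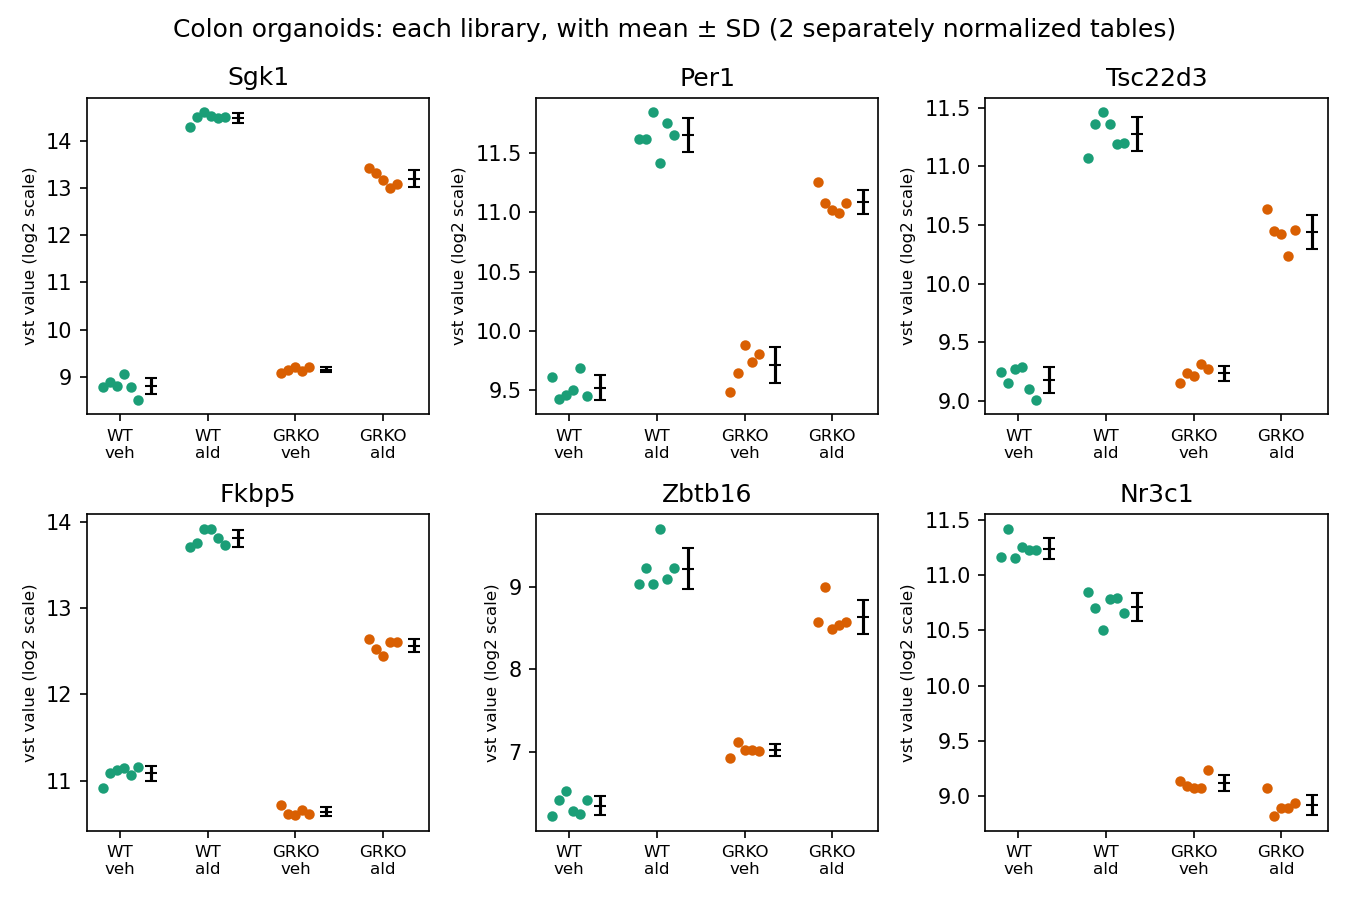
Library values (y axis, vst, log2 scale) of Sgk1, Per1, Tsc22d3, Fkbp5, Zbtb16 and Nr3c1 in each vehicle (veh) and aldosterone (ald) library of WT (n = 6) and GRKO (n = 5) organoids, with the mean ± SD beside each group of points. Sgk1 goes from 8.81 to 14.48 in WT and from 9.15 to 13.20 in GRKO organoids, and Nr3c1 is at 11.24 and 9.12 in vehicle libraries. Both organoid tables were normalized separately, so the levels of WT and GRKO libraries cannot be compared by test.

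The aldosterone response was stronger in WT organoids than in those labelled GRKO for Angptl4 by 2.73 ± 0.095 (adjusted p = 7.2e-17), Depp1 by 2.51 ± 0.14, Icosl, a ligand of T cell costimulation, by 2.13 ± 0.084 (2.09 against -0.05) and Ly6m by 1.99 ± 0.19. It was stronger for Slc25a33, a mitochondrial nucleotide carrier, by 1.74 ± 0.087, Engase by 1.64 ± 0.12 (1.62 against -0.01) and Sgk1 by 1.63 ± 0.11. Zbtb16 (1.26 ± 0.14), Tsc22d3 (0.89 ± 0.1), Fkbp5 (0.80 ± 0.075) and Per1 (0.76 ± 0.1) also responded more strongly in WT organoids, whereas Klf9 differed by 0.18 ± 0.084 (adjusted p = 0.37). Responses were more negative in WT organoids for Cdkn2b (-0.93 ± 0.11), Phlda1 (-0.84 ± 0.13), Ppp1r3b, a glycogen-targeting phosphatase subunit (-0.79 ± 0.16), and Nr3c1 (-0.32 ± 0.087, but -0.26 in the authors' deposited table, adjusted p = 0.33 by the z test). Of 40 corticosteroid-induced genes 26 had a higher response in WT organoids (medians 0.74 and 0.175), as did 7 of 35 transport genes (medians 0.165 and 0.15), 6 of 19 p53 genes and 5 of 26 metabolism genes, while 1 p53 gene and 1 metabolism gene had a lower response. In all, 363 genes were higher and 138 lower of 19375 tested. Over 872 genes raised on average the median response was 0.416 in WT and 0.158 in GRKO organoids, larger in WT for 792 (adjusted p = 4.9e-10 by limma's fry). Over 485 genes lowered on average it was -0.285 and -0.117 (adjusted p = 1.6e-11 by fry). Both organoid lines shared 189 raised genes, of 849 and 224 called among the genes tested in both (9.8 for independent lists), and 16 lowered genes (0.96 for independent lists).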

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

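The tests of compression, of the Nr3c2 level, of a common factor and of exchanged line labels were chosen only after the smaller responses had been seen, whereas the tests of the differences between responses and the other splits of the samples were planned.

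Several responses differed between lines by the test of the difference itself. Between parental MR cells and MR cells labelled GRKO the aldosterone response differed for 33 genes, among them Tsc22d3 (0.74), Per1 (0.27), Fkbp5 (0.19) and Klf9 (0.17). The corticosterone response differed between these lines for 359 genes, with Tsc22d3 at 1.80, Per1 at 0.86, Fkbp5 at 0.85, Sgk1 at 0.61, Dusp1 at 0.51, Klf9 at 0.42 and Nr3c1 at -0.19. Against parental cells without MR 70 genes differed (42 to 90 without single libraries), with 0.99 for Tsc22d3, 0.55 for Sgk1, 0.48 for Per1, 0.28 for Fkbp5 and 0.26 for Klf9. In the cells labelled GRKO, MR and MR580C differed for 76 genes (24 to 1751 without single libraries), with Sgk1 at 0.23 and Per1 at -0.55, where the authors' deposited table gives a Per1 difference of -0.26 (adjusted p = 0.5 by the z test). The z test gave 127 genes between both MR580C lines, with Tsc22d3 at 1.27 and Per1 at 1.03, and 27 between both parental lines. Under other processing these counts ran from 4 to 188 and from 2 to 28. The count between MR580C lines is too lenient, since the deposited p-values counted the repeated library as 2. WT and GRKO organoids differed for 501 genes, with Sgk1 at 1.63, Zbtb16 at 1.26, Tsc22d3 at 0.89, Fkbp5 at 0.80, Per1 at 0.76 and Nr3c1 at -0.32 (adjusted p = 0.33 by the z test).

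The aldosterone response over genes raised on average was smaller in organoids and MR cells labelled GRKO than in their counterparts, while over lowered genes the difference in size between the MR lines (-0.0436) turned to 0.0139 without vehicle 2 of the line labelled GRKO. Over the raised genes, the fold changes of the authors' deposited table, which are not made from the compressed library values, still differed by a median of 0.32 in organoids and 0.25 in cells, which argues against compression as the cause, and Nr3c2 stood 1.7 and 2.4 percentile points higher in the lines labelled GRKO, which argues against a lower MR transcript level. A smaller share of responding cells would shrink all excesses over vehicle by 1 factor if all raised genes responded in the same cells. On the fold changes of the authors' deposited table, 12.6% of 870 genes in organoids and 17.7% of 124 in cells departed from the common factor (0.37 and 0.41). Some organoid genes lay above it in that table, such as Slc9a3 with 77.7% and Fkbp5 with 53.7% of the WT excess kept. Others lay below it, such as Angptl4 with 8.11% and Depp1 with 7.58%. This argues against a single shared factor as the whole cause, not as a part of it. Genes that respond in different cells could shrink by different factors, so fewer responding cells of 1 type are not excluded. The loss of GR, which the labels name, may be the cause, as a hypothesis that could not be separated from other differences between lines. Each contrast sets 1 line against another, the labels give both MR lines different codes and MR protein was not measured. Nr3c1 reads were not lower in the MR cells labelled GRKO. A smaller response was also not shown between the MR580C lines. In the authors' deposited table their medians over 201 genes raised on average were 0.206 in parental cells and 0.26 in those labelled GRKO. The response was larger in parental cells for 87 of these genes. Limma across both scales gave a median difference of 0.112, so no direction is given for this pair.

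Of the splits of the organoid libraries drawn, only the real one gave as many genes for WT (1 of 100, 1330 genes against at most 212) and for GRKO (1 of 100, 263 against at most 14). For their difference the line labels were exchanged within vehicle and within aldosterone libraries, each gene being centred in each line. Only the real labels gave as many (1 of 100, 501 against at most 3). Other splits and exchanges mix a real effect into the spread within groups, which can lower their counts. A chance split of the organoid samples is therefore unlikely but not excluded. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For aldosterone in parental MR580C cells 1 split reached the real value of 216 (highest other 116), for corticosterone 1 (1300, highest other 0), for corticosterone against aldosterone 1 (630, highest other 1) and for aldosterone without MR 1 (1, highest other 0). In MR cells labelled GRKO 2 of the 10 splits called as many genes as aldosterone did (124, highest other 173) and 2 as many as corticosterone did (31, highest other 321). The former split sets vehicle 1 and 3 with aldosterone 3 against vehicle 2 with aldosterone 1 and 2. The latter sets vehicle 1 and 3 with corticosterone 1 against vehicle 2 with corticosterone 2 and 3 and calls several times the real count, which points to a structure of the samples that the groups do not explain.

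Single organoid libraries stood far from the others of their group in 8 of 64 tests, and chance alone gives about 5%. In WT vehicle libraries Fkbp5 was 10.92 in library 1 (others 11.07 to 11.16), Nr3c1 11.42 in library 2 (11.15 to 11.25) and the mean of the stem cell markers 9.35 in library 4 (9.47 to 9.54). In WT aldosterone libraries Zbtb16 was 9.70 in library 4 (9.03 to 9.23) and the stem cell mean 9.30 in library 4 (9.49 to 9.57). In GRKO organoids Klf9 was 9.89 in vehicle 1 (10.09 to 10.16) and 10.61 in aldosterone 1 (10.34 to 10.40), and Zbtb16 8.99 in aldosterone 2 (8.49 to 8.57).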

How the results depend on the processing

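The alternatives added after seeing the data are the authors' deposited adjusted p-value, centred library medians, genes above the median, the z test on 1 scale, limma across both scales, the repeated library counted as 2, and those that leave out both libraries numbered 3, GRKO organoid vehicle 1 and 2 or histone genes. The WT organoid count stayed within 1.5 times 1330 under its 17 alternatives (1113 to 1645), the count of genes that differ between organoid lines within 1.5 times 501 under its 28 (406 to 649). The size of that difference kept its direction under 28 alternatives for raised genes (0.233 to 0.323) and for lowered genes (-0.256 to -0.165). So did the size over raised genes of the MR lines under 17 (0.0808 to 0.253). Their calls held as well, except that the medians of the deposited fold changes, 1 of the alternatives in each case, had no test. Single genes were followed only where named, and 401 called entries of gene and comparison gave 5342 values. Of these 4888 kept direction and call, 421 kept direction only, 0 changed direction and 33 were not tested. Many were picked for large differences, and the top genes of each hormone comparison also for libraries that do not overlap. Leaving out 1 library cannot reverse those top genes, so these values do not describe all called genes. For named genes not called, 803 of 900 values stayed so, 26 passed and 58 changed sign, to values between -0.11 and 0.08. Centring moved no split of raised against lowered calls by more than 10 points. Count models, other scaling factors and another pseudocount were not run, since the values are logs, no filter removes nothing from the vst tables, and libraries could not be left out of the z tests.

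Without single libraries the counts ranged from 63 to 436 (aldosterone) and 14 to 177 (corticosterone) in MR cells labelled GRKO, 37 to 117 and 241 to 370 in parental MR cells, 0 to 49 without MR, 5 to 2377 in MR580C cells labelled GRKO, 80 to 287 and 761 to 1746 in parental MR580C cells, with 380 to 680 between hormones, and 171 to 970 in GRKO organoids. Between parental MR cells and those without MR they ranged from 42 to 90 and between MR and MR580C in lines labelled GRKO from 24 to 1751. The size over lowered genes of the MR lines, -0.0436, ranged from -0.0709 to 0.0139. Where an arm kept 1 library, it was assumed to vary like the others. The cause was not tested, except that fewer libraries give wider errors.

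Outside parental MR cells, no line had every pair of same-numbered libraries correlated over 0.1 or every library best with its own number, with correlations from -0.15 to 0.16 (aldosterone) and -0.09 to 0.34 (corticosterone) in MR cells labelled GRKO, -0.30 to -0.05 without MR, -0.18 to -0.02 in MR580C cells labelled GRKO, -0.23 to 0.28 (aldosterone) and 0.03 to 0.09 (corticosterone) in parental MR580C cells, -0.17 to 0.51 in WT and -0.16 to -0.08 in GRKO organoids. The 2 pairs per hormone of parental MR cells correlated at 0.70 to 0.75 and 0.67 to 0.72, each best with its own number, a hint from too few pairs. With the replicate number as a block, aldosterone called 252 genes in MR cells labelled GRKO, 365 in parental MR cells, 0 without MR and 19 in GRKO organoids, and corticosterone called 66 and 1257 in both MR lines. The block gave 250 and 739 differences between these lines for aldosterone and corticosterone, 36 against cells without MR, overlaps of 75 (aldosterone in both MR lines), 51 and 323 (both hormones in MR cells labelled GRKO and in parental MR cells), and a size of -0.0202 over lowered genes (no longer called). It moved no other count by over 1.5 times, except where scales differ.

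By the authors' deposited adjusted p 78 genes passed for corticosterone in MR cells labelled GRKO, 18 without MR, 553 in MR580C cells labelled GRKO and 468 in GRKO organoids. Genes above the median alone gave 24 for MR580C labelled GRKO, 46 for MR against MR580C and -0.0682 for the size over raised genes between MR580C lines. Leaving out histone genes, Rn45s and Rmrp left 81 of 124 by construction. Leaving out both libraries numbered 3 gave 207 and 840 in parental MR cells, 53 and 41 against the other MR line and cells without MR, and -0.011 over lowered genes (no longer called). The repeated library counted as 2 gave 683, by a spread that is too small. Without GRKO organoid vehicle 1 and 2, 1025 genes were called. The z test gave 131 for MR against MR580C. Limma across both scales gave 27 between MR580C lines (4 with the block), 7 between parental lines (2 with the block), and sizes of 0.112 and -0.0655 over raised and lowered genes, against -0.0431 and 0.0897. With an estimated correlation 8 lists were called. Apart from the constructions named, the cause was not tested.

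Values that changed sign were small and not called. Across both scales, parental MR minus parental MR580C gave 0.00 for Dusp1 (-0.01 with the block), -0.05 for Fkbp5 (-0.05), -0.10 for Klf9 (-0.11) and, with the block, 0.00 for Sgk1, and Nr3c2 was 0.08 (0.07) between MR580C lines. Without GRKO organoid vehicle 1 and 2, Nr3c2 was -0.07 and Scnn1a -0.02, with differences of 0.08 and 0.01 from WT. Sgk1 between the MR lines was 0.03 without both libraries numbered 3 and 0.06 by the z test, and -0.08 to 0.03 without single libraries. Scnn1a in parental MR580C cells was 0.00 centred and -0.03 to 0.03 without single libraries. The ranges without single libraries were -0.01 to 0.02 (Dusp1), -0.04 to 0.01 (Fkbp5), -0.01 to 0.00 (Nr3c2), -0.01 to 0.07 (Sgk1) and 0.00 to 0.03 (Tsc22d3) without MR, -0.05 to 0.12 (Dusp1), -0.03 to 0.03 (Nr3c2) and -0.04 to 0.03 (Scnn1a) in WT organoids. For Nr3c2 they were -0.03 to 0.05 in GRKO organoids, -0.05 to 0.04 between organoid lines, -0.03 to 0.07 in parental MR cells, -0.03 to 0.07 against cells without MR and -0.02 to 0.11 for corticosterone between MR lines, and for Nr3c1 -0.02 to 0.04 between MR and MR580C.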

Other observations

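The tests chosen only after the results were seen are the overlaps between systems, the matched random lists, the correlation of the libraries numbered 3 and the comparison of transport with metabolism genes, whereas the enterocyte markers and the correlation without the genes that deviate most had their predictions written before.

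Aldosterone raised 9 genes in all of parental MR cells, MR cells labelled GRKO, WT organoids and GRKO organoids, namely Sgk1, Per1, Tsc22d3, Spsb1, Bcl2l1, Ccn2, Gcnt2, Plk3 and Lurap1l. In the order of these groups, the authors' deposited table gives log2 fold changes of 0.95, 0.89, 6.08 and 4.59 for Sgk1, 2.49, 1.54, 2.32 and 1.60 for Per1, and 1.89, 0.55, 2.35 and 1.52 for Tsc22d3. In the same table Spsb1, an adaptor of a ubiquitin ligase, stands at 1.45, 0.68, 2.88 and 0.93, Ccn2, a matricellular growth factor, at 1.67, 0.92, 1.27 and 0.75, and Bcl2l1, an inhibitor of apoptosis, at 0.93, 0.40, 0.78 and 0.33. For Plk3, a polo-like kinase, the authors' deposited table holds 0.50, 0.32, 0.88 and 0.81, for Gcnt2, an enzyme that branches glycans, 0.92, 0.52, 1.26 and 0.69, and for Lurap1l 0.51, 0.22, 0.58 and 0.43.

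Parental MR cells and WT organoids shared 42 raised genes, of 77 and 595 called among 12330 genes tested in both, where independent lists would share 3.7, and 3 lowered genes of 8 and 297 (0.19). MR cells labelled GRKO and GRKO organoids shared 9 raised genes, of 54 and 146 (0.64), and 0 lowered genes, of 70 and 17 (0.097). With both receptor forms in parental cells 49 raised genes were shared, of 78 and 129 (0.81), and 5 lowered genes, of 9 and 80 (0.058). The 3 pairs have no library in common.

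Genes of Paneth cells, the antimicrobial secretory cells of the small intestine, stood higher above the lowest value of the table in vehicle GRKO organoids than in WT. Lyz1 was 3.31 ± 0.29 (SD, n = 6) above it in WT and 4.78 ± 0.92 (SD, n = 5) in GRKO, and Defa17 1.08 ± 0.32 and 3.61 ± 1.5, with the highest values in GRKO vehicle 1 and 2, while Ang4 (-0.44) and Mmp7 (0.06) differed little or the other way. Over 10 such genes, listed after the organoid tables had been seen and each above that lowest value in WT organoids as well, the median difference was 0.72, at percentile 100 of 10000 random lists matched on level, which does not exclude the separate normalization because the list was picked with these tables in view. Over 9 enterocyte markers of the small intestine it was -0.28 (median SD between libraries 0.23, Apob -0.32, Ada -0.40), which argues against more small-intestinal enterocytes in GRKO than in WT cultures as the cause. The separate normalization of the tables stays open, more Paneth-like secretory cells in some GRKO cultures may be the source, as a hypothesis with no test of its own, and no difference between tables has a p-value here.

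In parental MR cells the deviations of vehicle 3 and aldosterone 3 from their group means correlated over 12479 genes at 0.75, and at 0.50 without the 100 genes that deviate most, among them Lars2 (3.15 and 1.80), Rn45s (1.85 and 1.05) and Mir6236 (1.04 and 0.89), which argues against a few abundant genes as the whole cause. Aldosterone has only libraries 1 and 3, whose deviations are equal and opposite, and vehicle 1 and aldosterone 1 correlated at 0.70, so these values do not single out the libraries numbered 3. Corticosterone 1 and 3 likewise correlated with vehicle 1 and 3, at 0.72 and 0.67. A batch shared by same-numbered libraries stays open, since the labels name no batch, and genes are not independent replicates. No biological explanation was tested.

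In organoids the transport genes may keep more of their response without GR than the metabolism genes, a hypothesis found in these data. Of the excess over vehicle in WT organoids, in the authors' deposited table, GRKO organoids kept a median of 53.8% over 18 transport genes raised on average and 27.7% over 12 metabolism genes (2-sided permutation p = 0.048, 100000 resamples, genes not being independent). Scnn1g kept 55.5%, Slc9a3 77.7% and Sgk1 34.5% in the authors' deposited table, against 8.11% for Angptl4 and 12.8% for Txnip. Shares are unstable where the WT fold change is small. Among transport genes Slc12a2 kept 248% (WT log2 fold change 0.12) and Slc26a3 212% (0.33), and among metabolism genes Irs1 kept 256% (0.31). Against the hypothesis, Slc12a3 kept 1.82% and Usp2 9.94%, while Ppargc1a kept 82.9% and Pck1 77.4% in the authors' deposited table. The p-value lies just under 0.05 for a pair of lists picked after their members had been seen, so it is weak evidence.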
